A study of Arabidopsis thaliana with 15 samples.

How the data were processed

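The series holds 15 Affymetrix arrays of Arabidopsis thaliana Col-0 leaves. Plants were grown at 22 °C with 8 h of light of 180 µmol m−2 s−1 and 16 h of dark per day. The 5 groups of 3 biological replicates were light at day 0 and, after 3 and 6 days, leaves of darkened plants (DP) and individually darkened leaves (IDL). Each replicate was a pool of 2 leaves of independent plants, and per the labels about 40 mg of leaf material was extracted and 6 µg of total RNA was used.

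The authors deposited 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes the R package oligo made the values. Its version, background correction, normalization and summary method are not given in the sources used here, nor are the reason for the linear scale and the choice of the 26676 probe sets. The deposited intensity values had array medians of 18.31 to 19.56, a range of 0.0952 on the log2 scale. The largest spread of a quantile between arrays was 0.29 on that scale, so the medians were close and other parts of the distribution less so. All values were above 0, and log2 was taken first. No detection calls or background values were used.

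The annotation that came with the series' table paired 16179 probe sets with exactly 1 gene, 588 with several genes and 9909 with none. Probe sets with exactly 1 gene were tested, with the brightest probe set standing for each of the 4 genes that had more than 1, which gave 16174 genes. No dim gene was left out. Symbols came from the RefSeq gene table of assembly TAIR10.1, matched by locus code, and 16067 of 16179 probe sets matched. Of the genes tested, 1625 carried a symbol, and others are named by their locus code. No coordinates are given.

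All 15 arrays were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean per group and a prior of 10.52 degrees of freedom. The 9 comparisons were each darkened group against light, IDL against DP at each day, day 6 against day 3 within each treatment, and the interaction of treatment and day. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg within the comparison, two-sided), and the number that changed at least 2-fold is given beside it. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of the comparison. Lists with fewer measured members were not tested, and their genes are given singly. Calls with an estimated correlation between genes are given beside those of the preset correlation. Counts adjusted over the list alone use the Benjamini-Hochberg method within the list. The comparisons, tests, gene lists, named-gene rule and other settings to be tried were chosen before the data were examined.

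Named genes were chosen by a rule. For comparisons with light and of IDL with DP it takes the 5 largest rises and 5 largest falls among called genes that carry a symbol and whose arrays do not overlap between both groups. It adds up to 4 called members of each described list with the largest change in each direction, from which examples are given. For changes over time and the interaction it takes 3 genes each way. It also takes 18 preset genes in every comparison, of which ICL and ATG8H were measured.

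The overlap of DP and IDL against light was set beside independent lists and beside 100 simulated sets of unchanged groups that share 3 controls. The steps were tested on simulated data with 50 genes given each of the 1.25, 1.5, 2 and 4-fold changes per comparison among 16174 genes in the fit. Between 1.5% and 6.6% of calls on simulated data were false, and a shifted list was called in each of the 9 comparisons. In DP at day 6 against light and in IDL against DP at day 3, 1 list that had not been shifted was called as well. Fewer genes were changed by design than were called in each real comparison, so the adjusted threshold was stricter there. The recovery rates thus do not give the sensitivity of the real comparisons. Noise was drawn independently for each gene, so the shifted list does not test the preset correlation. Other splits of the arrays were counted, 10 for each pair of groups and 100 drawn at random for the interaction and the overlap.

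Alternatives were an adjusted p under 0.01, an added 2-fold minimum, leaving out genes in the lowest quartile of mean level (the dim genes), the mean of probe sets per gene, centring on the median or on the reference genes, quantile normalization, an intensity trend with a robust prior, array weights, a fit of only the arrays compared, the replicate number as a block, leaving out each array in turn, and the estimated correlation. A fit of all probe sets, 10 wider gene lists and 29 families by symbol were added after the annotation had been read, because it covered 16.9% of the fixed lists' entries. Probe sets with several genes or none were left out of all other fits.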

Results

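Transcript levels were measured on 15 Affymetrix arrays in leaves of Arabidopsis thaliana, accession Col-0. The 5 groups had 3 biological replicates each, and every replicate pooled 2 leaves taken from independent plants at noon. Light leaves (day 0) came before any darkening. The other groups came from plants darkened as a whole in dark boxes (darkened plant, DP) or from single leaves under foil-coated covers on plants that stayed in light (individually darkened leaf, IDL), after 3 or 6 days. The values were deposited intensities on a linear scale, from 5.192 to 6632.8, and were converted to log2 here. The median of the 15 arrays lay between 18.31 and 19.56. Of 26676 probe sets, 16179 were paired with exactly 1 gene, which gave 16174 genes tested, and 1625 of these carried a gene symbol. A further 9909 probe sets had no gene in the annotation used here. Fixed gene lists of 35 pathways and cell types had 581 entries, of which 98 (16.9%) were measured. The 7 lists with at least 5 measured members were tested as lists, and the others were not. The number of arrays, 3 per group, limits the precision of each value. Light leaves were sampled at day 0 only, so in every comparison with light the darkness goes together with 3 or 6 more days of leaf age. Changes are given as log2 differences with their standard error, and n = 3 arrays per group throughout. The largest rises and falls named are those among called genes that carry a symbol and have no overlap of arrays, and genes without a symbol can exceed them. No background values were used. Light means of AGL104 (3.34), PAP20 (3.38), PDF1.4 (3.43), CML41 (3.44), NAI2 (3.55) and AtLEA4-1 (3.56) lay near or below the lower quartile of all genes in light (3.44). In IDL at day 6 the means of BZIP61 (3.45), NdhL (3.52) and XTH33 (3.58) lay near or below that group's lower quartile (3.46), as at day 3 did those of ZAT7 (3.17) and EXO (3.48), with a quartile of 3.51. Hsp70-2 (3.50) and IAA29 (3.57) lay there in DP at day 6, with a quartile of 3.51, and IAA29 also in IDL at day 3 (3.52) and day 6 (3.32). ICL lay near or below the quartile in light (3.36), in DP at day 3 (3.53) and in IDL at both days (3.45 and 3.43), so its values in all comparisons are limited by this level. Genes outside this selection lay there too. Changes measured from or to such levels are to be read as lower bounds on their size, and no fold is given for them. Adjusted p values of genes are from limma's moderated test, two-sided, and those of lists from limma's camera.

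The 15 arrays fell into their groups along the first principal component of the genes tested, which held 52.8% of the variance, and the second, which held 26.6%. Light arrays lay between -74.5 and -69.9 on the first component, DP arrays between 4.0 and 15.4, and IDL arrays between 20.3 and 32.7. On the second component DP arrays lay between -34.8 and -26.3 and IDL arrays between 13 and 35.1. Across all 26676 probe sets, which are not independent replicates, arrays of 1 group correlated at 0.984 to 0.991 and arrays of different groups at 0.805 to 0.981.

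**Figure D1:**
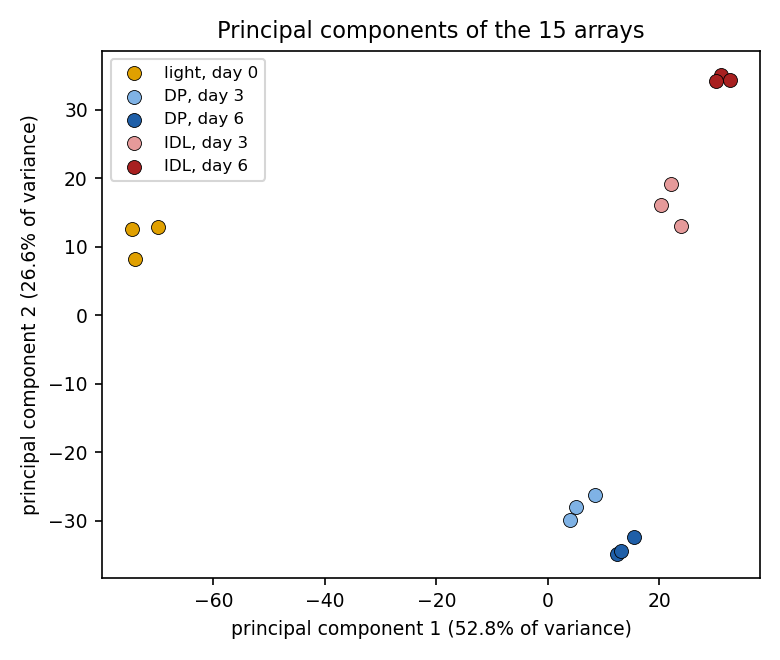
Each point is 1 of the 15 arrays, placed by its score on the first (horizontal axis, 52.8% of variance) and second principal component (vertical axis, 26.6%) and coloured by group. Light arrays (-74.5 to -69.9 on the first component) stand apart from all darkened arrays, and the second component separates DP (-34.8 to -26.3) from IDL (13 to 35.1).

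The comparison of DP at day 3 with light asks how leaf transcripts differ after 3 days of darkness on the whole plant. NAI2 (AT3G15950), a protein of endoplasmic reticulum bodies, rose by 5.30 ± 0.22 (adjusted p = 3.23e-14). The cold-regulated gene COR27 (AT5G42900) rose by 4.56 ± 0.18. WES1 (AT4G27260), which joins amino acids to auxin, rose by 4.16 ± 0.21. The methionine gamma-lyase MGL (AT1G64660) rose by 3.98 ± 0.15 and AKINBETA1 (AT5G21170), a subunit of the SnRK1 kinase, by 3.94 ± 0.12 (15.4-fold). Among genes with a symbol the largest falls were those of LrgB (AT1G32080), a plastid glycolate and glycerate transporter, which fell by 5.15 ± 0.13 (adjusted p = 1.97e-17), TBL26 (AT4G01080), which fell by 5.03 ± 0.18, the glutathione transferase GSTU20 (AT1G78370), which fell by 4.99 ± 0.16, the glycosyl hydrolase GH9C2 (AT1G64390), which fell by 4.44 ± 0.16, and NdhL (AT1G70760) of the plastid NDH complex, which fell by 4.34 ± 0.12. By the rule of choice, all 3 DP arrays lay on 1 side of all 3 light arrays in each of these 10 genes. The largest adjusted p was 8.94e-13.

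All 7 measured genes for light harvesting and photosystem subunits fell in DP at day 3, and 7 of 7 also fell when adjusted over the list alone. PSBW, a subunit of photosystem II, fell by 2.43 ± 0.15, and PSAE-1, a subunit of photosystem I, fell by 1.82 ± 0.16. The list's median was -1.30 (adjusted p = 1.02e-06). Of 9 measured genes of branched chain amino acid breakdown 6 rose and 3 did not pass, while 6 rose and 1 fell when adjusted over the list alone. MCCB, part of leucine breakdown, rose by 3.28 ± 0.14, and ETFQO, which passes electrons from this pathway to the respiratory chain, rose by 2.89 ± 0.13. The list's median was 1.31 (adjusted p = 4.85e-06). Of 6 genes of other amino acid breakdown 5 rose and 1 fell, also when adjusted over the list alone, with a median of 1.8 (adjusted p = 1.69e-05). In it AT4G33150, which acts in lysine breakdown, rose by 5.78 ± 0.13 (54.8-fold), while the urease gene URE fell by 0.58 ± 0.11. Autophagy genes rose in 11 of 13 cases (12 adjusted over the list alone) and fell in 1, with a median of 0.68 (adjusted p = 1.69e-05). ATG8B rose by 2.55 ± 0.12 and ATG8H, a preset gene, by 0.98 ± 0.14 (adjusted p = 9.38e-06), while AT3G61960, a kinase of the ATG1 type, fell by 0.52 ± 0.11.

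Senescence regulators and markers rose in 4 of 5 cases, also when adjusted over the list alone, with a median of 0.69 (adjusted p = 0.0026). The transcription factor WRKY22 rose by 2.75 ± 0.14 and EIN3, a factor of the ethylene response, by 1.44 ± 0.11. WRKY6 rose by 0.65 ± 0.20, and its call was lost without replicate 2 of DP at day 3 (0.39, adjusted p = 0.134). Of 8 genes of the tricarboxylic acid cycle and respiration 5 fell and 3 did not pass, also when adjusted over the list alone. IDH-VI, an isocitrate dehydrogenase subunit, fell by 0.99 ± 0.13 and the succinate dehydrogenase gene SDH1-1 by 0.97 ± 0.17. This list's median was -0.66 (adjusted p = 0.0165, but adjusted p = 0.0593 with an estimated correlation and 0.0553 after quantile normalization). Of 6 proteases and nucleases 3 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.217). AT1G02305 rose by 1.44 ± 0.20, and the vacuolar processing enzyme BETA-VPE fell by 2.24 ± 0.15. With an estimated correlation between genes 5 of the 7 lists held their call.

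Among lists too short to test, the 3 measured Calvin cycle genes fell, with SBPASE, PRK and RCA at -4.19, -1.40 and -1.92. The 3 measured genes of chlorophyll synthesis fell too, with PORB at -2.39, GSA1 at -1.32 and CHLM at -0.94. ATSPS4F, a sucrose phosphate synthase, fell by 3.95. The chloroplast cold-regulated gene COR15A fell by 2.96, and SDP1, a lipase of seed oil breakdown, rose by 1.41. ICL, the isocitrate lyase of the glyoxylate cycle, stood at 0.16 ± 0.12 (adjusted p = 0.351). Of the 2 measured guard cell markers AT1G22690 fell by 1.51, and FMA stood at 0.21 (adjusted p = 0.276). In all, 5694 of 16174 genes (35.2%) changed, 2785 higher and 2909 lower, and 1735 of them changed at least 2-fold. More genes were higher than lower after quantile normalization (3066 and 2634) and with centring on the reference genes (3688 and 2172). In simulated data of this comparison with 16174 genes in the fit, 42% of genes given a 1.5-fold change and 94% of those given a 2-fold change were recovered. Far fewer genes were changed there than were called here. These rates, like those of the comparisons below, therefore do not give the sensitivity in the real data.

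At day 6 of darkness the same question was asked of DP leaves. NAI2 rose by 6.36 ± 0.22 (adjusted p = 1.46e-15), COR27 by 5.26 ± 0.18 (38.2-fold), WES1 by 4.32 ± 0.21 and MGL by 4.23 ± 0.15. The defensin gene PDF1.4 (AT1G19610) rose by 3.99 ± 0.45 (adjusted p = 2.14e-07). LrgB fell by 5.15 ± 0.13, GSTU20 by 4.80 ± 0.16, TBL26 by 4.66 ± 0.18 and NdhL by 4.56 ± 0.12. FAMT (AT3G44860), a farnesoic acid methyltransferase, fell by 4.61 ± 0.21.

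The 7 light harvesting and photosystem genes all fell in DP at day 6, over all genes and adjusted over the list alone, with a median of -1.85 (adjusted p = 1.4e-07). PSBW fell by 4.0 ± 0.15 and PSAE-1 fell by 3.33 ± 0.16. Branched chain amino acid breakdown had 6 of 9 genes risen and 3 not passed (7 risen when adjusted over the list alone), with a median of 1.38 (adjusted p = 3.98e-05), MCCB at 3.10 ± 0.14 and ETFQO at 3.01 ± 0.13. Other amino acid breakdown had 4 of 6 genes risen and 1 fallen, also when adjusted over the list alone. AT4G33150 rose by 5.86 ± 0.13, and the list's median was 1.57 (adjusted p = 0.000739, but adjusted p = 0.0506 with an estimated correlation). Autophagy had 10 of 13 genes risen and 1 fallen, also when adjusted over the list alone. ATG8B rose by 2.2 ± 0.12 and ATG8H by 0.71 ± 0.14, while AT3G61960 fell by 0.69 ± 0.11. The median was 0.46 (adjusted p = 0.00271, but adjusted p = 0.0958 with an estimated correlation). Senescence regulators had 4 of 5 genes risen, also when adjusted over the list alone, with WRKY22 at 2.51 ± 0.14, EIN3 at 1.69 ± 0.11 and a median of 0.60 (adjusted p = 0.00595, and 0.0494 with an estimated correlation). In all, 3 of the 7 lists held their call with an estimated correlation. With arrays centred on the reference genes, the medians of autophagy and of senescence regulators were 0.81 and 0.95, and that of respiration genes went from -0.54 to -0.20.

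Respiration genes fell in 5 of 8 cases and rose in 1, also when adjusted over the list alone. AT3G55410 fell by 1.32 ± 0.13 and SDH1-1 by 1.22 ± 0.17, while AT5G65750 rose by 0.62 ± 0.13. The median was -0.54 (adjusted p = 0.0211, but adjusted p = 0.0817 with an estimated correlation and 0.0719 after quantile normalization). Proteases and nucleases had 2 genes risen and 1 fallen of 6, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.725). BETA-VPE fell by 2.16 ± 0.15 and AT4G01610 rose by 0.95 ± 0.16. SBPASE fell by 4.49, PORB by 2.91 and ATSPS4F by 4.01, while AKINBETA1 rose by 3.69. Of the guard cell markers AT1G22690 fell by 2.04 and FMA stood at 0.17 (adjusted p = 0.392). ICL rose by 0.37 ± 0.12 (adjusted p = 0.0203), a call that was lost without replicate 1 of DP at day 6 (0.28, adjusted p = 0.111), without replicate 1 of light (0.29, adjusted p = 0.0984) and after quantile normalization (0.31, adjusted p = 0.0593). In all, 6457 genes (39.9%) changed, 3280 higher and 3177 lower, and 2103 of them at least 2-fold. Centring on the reference genes moved the median of all genes to 0.40 and gave 9268 genes higher and 1908 lower, while centring on the median gave 3064 and 3315. Simulated data of this comparison, with 16174 genes in the fit, gave a recovery of 54% at 1.5-fold and 94% at 2-fold.

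Leaves darkened individually for 3 days were compared with light to ask how transcripts differ when darkness is limited to the leaf. WES1 rose by 4.93 ± 0.21 (30.5-fold). The late embryogenesis gene AtLEA4-1 (AT1G32560) rose by 3.85 ± 0.20, the calmodulin-like gene CML41 (AT3G50770) by 3.82 ± 0.26, COR27 by 3.81 ± 0.18 and the MADS box gene AGL104 (AT1G22130) by 3.67 ± 0.16. COR15A (AT2G42540) fell by 5.52 ± 0.22 (adjusted p = 1.21e-14), NdhL by 5.48 ± 0.12 and SBPASE (AT3G55800), an enzyme of the Calvin cycle, by 5.24 ± 0.13. LrgB fell by 4.83 ± 0.13 and TBL26 by 4.82 ± 0.18. The largest adjusted p among these 10 genes was 6.9e-11.

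All 7 light harvesting and photosystem genes fell in IDL at day 3, over all genes and adjusted over the list alone, with PSBW at -2.73 ± 0.15, LHCB4.2 at -2.48 ± 0.15 and a median of -2.18 (adjusted p = 2.46e-07). All 13 autophagy genes rose, over all genes and adjusted over the list alone. ATG8B rose by 3.06 ± 0.12, APG8A by 2.23 ± 0.12, ATG8E by 2.18 ± 0.13 and ATG8H by 1.89 ± 0.14, and the median was 1.2 (adjusted p = 1.97e-09). Branched chain amino acid breakdown had 7 of 9 genes risen and 1 fallen (8 and 1 when adjusted over the list alone), with a median of 2.11 (adjusted p = 3.41e-06). MCCB rose by 3.02 ± 0.14 and AT4G31810 fell by 0.67 ± 0.16. Other amino acid breakdown had 5 of 6 genes risen and 1 fallen, also when adjusted over the list alone, with a median of 3.04 (adjusted p = 5.59e-06). AT4G33150 rose by 6.03 ± 0.13 and AT5G38710, which acts in proline breakdown, by 3.30 ± 0.15. Senescence regulators had 4 of 5 genes risen, also when adjusted over the list alone, with EIN3 at 1.60 ± 0.11 and WRKY6 at 0.98 ± 0.20. Their median was 0.59 (adjusted p = 0.0367), but the call was lost without replicate 2 of light (0.58, adjusted p = 0.052) and at an adjusted p = 0.0835 with an estimated correlation, with which 4 of the 7 lists held theirs.

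Proteases and nucleases had 5 of 6 genes risen and 1 fallen, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.0603). It passed after quantile normalization (adjusted p = 0.0449) and without replicate 3 of light (adjusted p = 0.0369). GAMMA-VPE rose by 2.11 ± 0.19, and BETA-VPE fell by 1.98 ± 0.15. In the respiration list 1 of 8 genes fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.82). The alpha-amylase AMY1 rose by 3.23, and NOL, which reduces chlorophyll b, by 1.02. PRK fell by 3.65, PORB fell by 2.86 and ATSPS4F fell by 0.68. ICL stood at 0.08 ± 0.12 (adjusted p = 0.639). AT1G22690, a guard cell marker, fell by 2.46, and the other, FMA, stood at 0.30 (adjusted p = 0.0995). In all, 6400 genes (39.6%) changed, 3365 higher and 3035 lower, and 2018 of them at least 2-fold. Centring on the reference genes moved the median of all genes to 0.25 and gave 5652 genes higher and 2115 lower. In simulated data with 16174 genes in the fit, recovery for this comparison was 60% at 1.5-fold and 96% at 2-fold.

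For IDL at day 6 against light, WES1 rose by 5.09 ± 0.21 (34.0-fold) and the purple acid phosphatase gene PAP20 (AT3G52780) by 4.98 ± 0.17 (adjusted p = 1.42e-15). AtLEA4-1 rose by 4.93 ± 0.20. CHAT (AT3G03480), an acetyltransferase that makes a green leaf volatile, rose by 4.14 ± 0.23 and AMY1 (AT4G25000) by 4.09 ± 0.23. NdhL fell by 6.14 ± 0.12 (adjusted p = 3.63e-19), ECS1 (AT1G31580) by 6.12 ± 0.33, LrgB by 5.52 ± 0.13, SBPASE by 5.51 ± 0.13 and GH9C2 by 5.13 ± 0.16.

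The 7 light harvesting and photosystem genes fell in IDL at day 6, over all genes and adjusted over the list alone, with PSBW at -3.16 ± 0.15, PSAN at -2.83 ± 0.15 and a median of -2.63 (adjusted p = 1.03e-07). All 13 autophagy genes rose, over all genes and adjusted over the list alone. ATG8B rose by 3.20 ± 0.12, ATG8H by 2.64 ± 0.14 (6.24-fold) and APG8A by 2.25 ± 0.12, with a median of 1.25 (adjusted p = 3e-09). Branched chain amino acid breakdown had 7 genes risen and 1 fallen of 9, also when adjusted over the list alone, with ALDH6B2 at 2.34 ± 0.13 and a median of 1.81 (adjusted p = 1.61e-05). Other amino acid breakdown had 5 of 6 genes risen and 1 fallen, also when adjusted over the list alone, with AT4G33150 at 6.06 ± 0.13, AT5G38710 at 3.61 ± 0.15 and a median of 2.91 (adjusted p = 1.61e-05). Senescence regulators had 4 of 5 genes risen, also when adjusted over the list alone, with EIN3 at 1.5 ± 0.11 and a median of 0.93 (adjusted p = 0.0142, and 0.0475 with an estimated correlation). SAG29 of this list did not pass (-0.08, adjusted p = 0.647). All 5 lists with a call at this day held it with an estimated correlation.

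Proteases and nucleases had 3 genes risen and 1 fallen of 6, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.225). AT4G01610 rose by 2.09 ± 0.16 and GAMMA-VPE by 2.01 ± 0.19. Respiration genes rose in 3 of 8 cases and fell in 1, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.35). The cytochrome c gene CYTC-2 rose by 1.18 ± 0.18, and AT3G55410 fell by 0.84 ± 0.13. PRK fell by 4.25, PORB by 3.52 and CHLM by 2.88. ICL stood at 0.07 ± 0.12 (adjusted p = 0.726), and passed only when arrays were centred on the reference genes (0.47, adjusted p = 0.00375). The guard cell marker AT1G22690 fell by 3.16, and FMA rose by 0.40 (adjusted p = 0.0289), a call lost without replicate 3 of light (0.33, adjusted p = 0.115) and without replicate 2 of IDL at day 6 (0.31, adjusted p = 0.143). Of the reference genes GAPC2 fell by 1.67, and PEX4 rose by 0.48. In all, 6422 genes (39.7%) changed, 3334 higher and 3088 lower, and 2270 of them at least 2-fold. Centring on the reference genes moved the median of all genes to 0.42 and gave 10006 genes higher and 1764 lower. Few reference genes were measured, so this shift came largely from the fall of GAPC2. Simulated data with 16174 genes in the fit gave a recovery for IDL at day 6 of 60% at 1.5-fold and 98% at 2-fold.

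**Figure D2:**
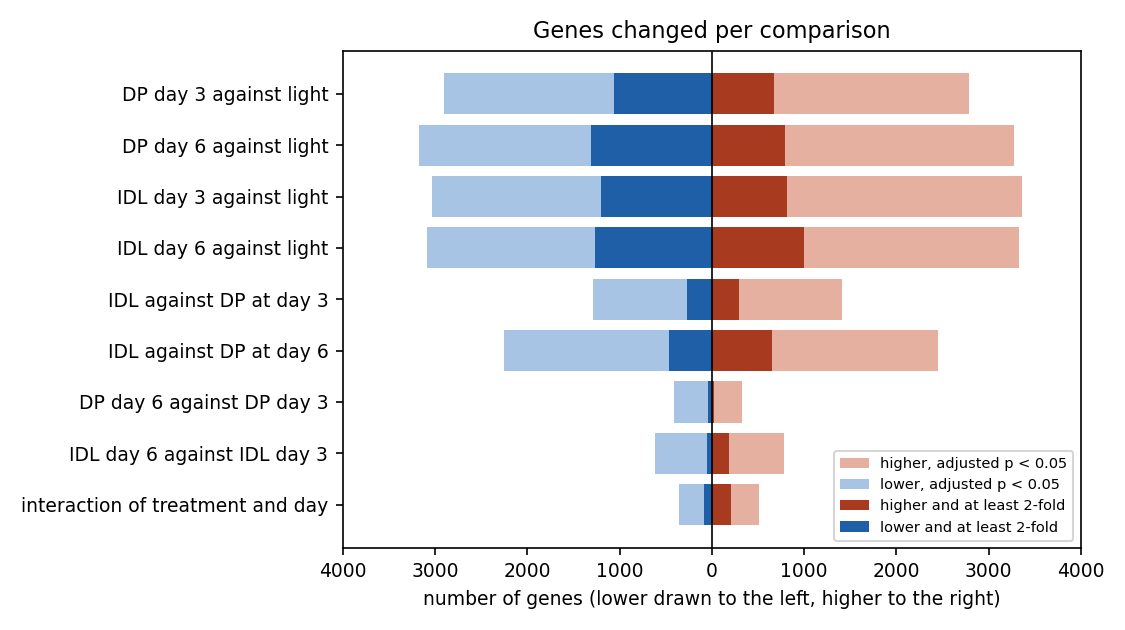
Bars give the number of genes, of 16174 tested, (horizontal axis) that were higher (to the right) or lower (to the left) at an adjusted p under 0.05 in each comparison (vertical axis), with the darker part showing those that changed at least 2-fold. Comparisons with light held 5694 to 6457 changed genes, IDL against DP held 2705 at day 3 and 4699 at day 6, and day 6 against day 3 held 738 in DP and 1398 in IDL.

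**Figure D3:**
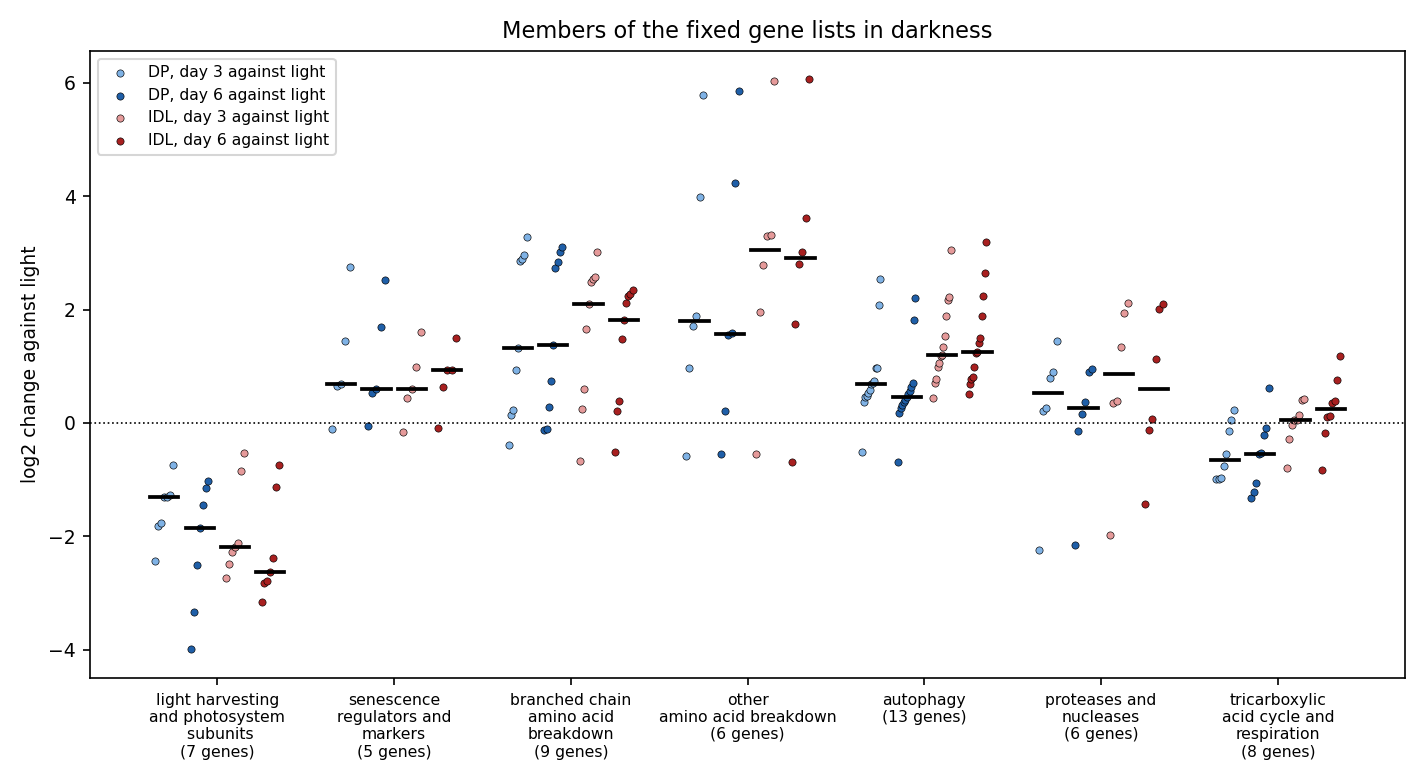
Points are the measured members of the 7 tested gene lists (horizontal axis), placed by their log2 change against light (vertical axis) in DP (blue) and IDL (red) at day 3 (pale) and day 6 (dark), each from 3 against 3 arrays, and black lines are medians. Light harvesting and photosystem medians lay between -1.30 and -2.63, and autophagy medians were 0.68 and 0.46 in DP against 1.2 and 1.25 in IDL.

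The comparisons with light shared many genes between treatments. At day 3, 2024 genes were higher and 2341 lower in both DP and IDL, and 131 changed in opposite directions. Independent lists of these lengths would share 579.4 higher and 545.9 lower genes. At day 6, 1913 genes were higher and 2320 lower in both, and 294 went opposite ways, against 676.1 and 606.6 for independent lists. Log2 changes correlated across genes at 0.839 at day 3 and 0.756 at day 6. Both comparisons use the same 3 light arrays, and these were not split, since 3 do not give at least 2 to each comparison, so part of the excess may come from shared controls. In 100 simulated sets of unchanged groups against shared controls the median number of genes called in the same direction was 0, with at most 2 at day 3 and 1 at day 6, and the median correlation was 0.522 and 0.519. With unchanged groups hardly any gene can be called. That count therefore does not show how far shared controls add to the real overlap. The covariance of the changes was 0.452 at day 3 and 0.494 at day 6, against simulated medians of 0.0113 and 0.0111. The highest simulated values were 0.0233 and 0.0226. These values argue against noise of the shared light arrays as the main source of the covariance. They do not give its part in the count of shared genes, and a shift common to all light arrays would not show in them.

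IDL and DP leaves were compared directly at day 3 to ask whether darkening a single leaf differs from darkening the plant. AMY1 was 3.46 ± 0.23 higher in IDL (11-fold, adjusted p = 5.15e-10). The serine carboxypeptidase-like gene scpl48 (AT3G45010) was 3.43 ± 0.16 higher, ATSPS4F (AT4G10120) 3.28 ± 0.15, CHAT 3.10 ± 0.23 and the glycosyltransferase UGT87A2 (AT2G30140) 2.64 ± 0.29. NAI2 was lower in IDL, at -5.18 ± 0.22 (adjusted p = 2.82e-12). CSLC04 (AT3G28180), which makes the xyloglucan backbone, stood at -3.81 ± 0.17, the bZIP factor gene BZIP61 (AT3G58120) at -3.41 ± 0.26, EXO (AT4G08950) at -3.08 ± 0.18, and FHL (AT5G02200), which carries phytochrome A to the nucleus, at -3.03 ± 0.15.

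Autophagy genes were higher in IDL than in DP at day 3 in 10 of 13 cases (11 adjusted over the list alone), and 3 did not pass. APG8A was 1.26 ± 0.12 higher, AT3G61960 0.97 ± 0.11, ATG8H 0.91 ± 0.14 and AT5G66930 0.88 ± 0.12. The list's median was 0.52 (adjusted p = 3.85e-08, and 0.0362 with an estimated correlation), and this was the list of the 7 that held its call with an estimated correlation. Respiration genes were higher in 4 of 8 cases, also when adjusted over the list alone, with CYTC-2 at 1.18 ± 0.18 and SDH1-1 at 0.93 ± 0.17. The median was 0.45 (adjusted p = 0.00434, but adjusted p = 0.0537 with an estimated correlation). Light harvesting and photosystem genes were lower in 3 of 7 cases and higher in 1 (4 and 1 when adjusted over the list alone), with PSAN at -0.88 ± 0.15, PSBY at -0.85 ± 0.13 and LHCB4.2 at -0.72 ± 0.15. LHCB4.3 was 0.46 ± 0.16 higher (adjusted p = 0.0482), a call lost without replicate 2 of DP at day 3 (0.35, adjusted p = 0.211) and without 4 other arrays. The list's median was -0.46 (adjusted p = 0.0298), lost without replicate 3 of DP at day 3 (-0.41, adjusted p = 0.0623) and at an adjusted p = 0.094 with an estimated correlation.

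Other amino acid breakdown had 2 of 6 genes higher and 1 lower in IDL at day 3, also when adjusted over the list alone. AT5G38710 was 2.32 ± 0.15 higher and the ornithine aminotransferase gene DELTA-OAT 1.09 ± 0.11 higher, while MGL stood at -0.66 ± 0.15. The median was 0.16 (adjusted p = 0.0388, but adjusted p = 0.202 with an estimated correlation). This call was also lost without replicate 1 (0.14, adjusted p = 0.0605) or replicate 3 of DP (0.10, adjusted p = 0.0623), without replicate 2 of IDL (0.08, adjusted p = 0.0902), with the dim genes left out (adjusted p = 0.0591) and with only the arrays compared in the fit (adjusted p = 0.0655). Proteases and nucleases were higher in 2 of 6 cases, also when adjusted over the list alone, with GAMMA-VPE at 1.32 ± 0.19 and AT4G01610 at 1.03 ± 0.16. Their median was 0.21 (adjusted p = 0.0298), lost without replicate 1 of DP at day 3 (0.08, adjusted p = 0.0605) and at an adjusted p = 0.184 with an estimated correlation. Branched chain amino acid breakdown had 3 genes higher and 1 lower of 9, also when adjusted over the list alone. The list did not pass (adjusted p = 0.836), with a median of -0.26 but a mean of 0.04. AT4G20930 was 0.79 ± 0.13 higher. Of the senescence regulators WRKY22 was lower at -2.16 ± 0.14, the other 4 did not pass, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.145). PRK stood at -2.25, COR15A at -2.56, CHLM at -0.96 and the guard cell marker AT1G22690 at -0.95, while NOL was 1.22 higher. FMA, the other guard cell marker, stood at 0.09 (adjusted p = 0.79). ICL stood at -0.08 ± 0.12 (adjusted p = 0.779). In all, 2705 genes (16.7%) differed, 1413 higher and 1292 lower in IDL, and 564 of them at least 2-fold. The split turned to 1291 higher and 1387 lower with centring on the median and was 1415 and 889 with centring on the reference genes. Simulated data of IDL against DP at day 3, with 16174 genes in the fit, gave a recovery of 72% at 1.5-fold and 96% at 2-fold.

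At day 6, PAP20 was 4.60 ± 0.17 higher in IDL than in DP (adjusted p = 5.19e-14), AMY1 4.33 ± 0.23, CHAT 4.2 ± 0.23, scpl48 4.12 ± 0.16 and ATSPS4F 3.49 ± 0.15. NAI2 was lower, at -5.74 ± 0.22, as were BZIP61 at -3.47 ± 0.26, PDF1.4 at -2.95 ± 0.45 (adjusted p = 2.59e-05), the xyloglucan endotransglucosylase gene XTH33 (AT1G10550) at -2.92 ± 0.18 and CSLC04 at -2.58 ± 0.17. Autophagy genes were higher in IDL in 10 of 13 cases, also when adjusted over the list alone. ATG8H (AT3G06420) stood at 1.94 ± 0.14, APG8A at 1.61 ± 0.12, AT3G61960 at 1.47 ± 0.11 and APG8H, a gene other than ATG8H, at 1.05 ± 0.13. The median of the autophagy list was 0.92 (adjusted p = 3.74e-08, and 0.0237 with an estimated correlation). Respiration genes were higher in 6 of 8 cases and lower in 1, also when adjusted over the list alone. CYTC-2 was 1.71 ± 0.18 higher, SDH1-1 1.57 ± 0.17, the alternative NADH dehydrogenase gene NDB2 1.32 ± 0.16 and IDH-VI 0.88 ± 0.13, with a median of 0.75 (adjusted p = 0.000592, and 0.0237 with an estimated correlation).

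Proteases and nucleases were higher in IDL at day 6 in 3 of 6 cases, also when adjusted over the list alone, with GAMMA-VPE at 1.65 ± 0.19, AT4G01610 at 1.14 ± 0.16 and BETA-VPE at 0.72 ± 0.15. Their median was 0.47 (adjusted p = 0.041, but adjusted p = 0.248 with an estimated correlation). This call was also lost without replicate 2 of DP (0.38, adjusted p = 0.083), without replicate 1 of IDL (0.45, adjusted p = 0.0511), after median centring (adjusted p = 0.0508), after quantile normalization (adjusted p = 0.0548) and with the dim genes left out (adjusted p = 0.0737). Branched chain amino acid breakdown had 3 genes higher and 4 lower of 9 (3 and 5 when adjusted over the list alone), with D2HGDH at 0.73 ± 0.11, MCCB at -0.87 ± 0.14 and ETFQO at -0.73 ± 0.13, and the list did not pass (adjusted p = 0.509). Other amino acid breakdown had 2 of 6 genes higher and 1 lower, also when adjusted over the list alone, with AT5G38710 at 3.41 ± 0.15 and MGL at -1.22 ± 0.15, and did not pass as a list (adjusted p = 0.163). Light harvesting and photosystem genes were higher in 2 of 7 cases and lower in 2 (3 and 2 when adjusted over the list alone). PSBW was 0.84 ± 0.15 higher and PSAN stood at -0.99 ± 0.15, and the list did not pass (adjusted p = 0.954), with a median of 0.02 but a mean of -0.05. Of the senescence regulators WRKY22 was lower at -1.58 ± 0.14, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.491), with a median of -0.04 that turned positive under each of 3 scalings, at most 0.02. PRK stood at -2.57, CHLM at -1.60, COR15A at -1.60, GAPC2 at -1.04 and AT1G22690 at -1.12, while NOL was 1.47 higher and FMA stood at 0.23 (adjusted p = 0.259). ICL stood at -0.30 ± 0.12 (adjusted p = 0.0777). It passed without replicate 3 of DP at day 6 (-0.38, adjusted p = 0.0442). In all, 4699 genes (29.1%) differed, 2450 higher and 2249 lower in IDL, and 1115 of them at least 2-fold. The split turned to 2314 higher and 2400 lower after quantile normalization and was 2726 and 1933 with centring on the median and 2431 and 1585 with centring on the reference genes. Recovery in simulated data of IDL against DP at day 6, with 16174 genes in the fit, was 50% at 1.5-fold and 100% at 2-fold.

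**Figure D4:**
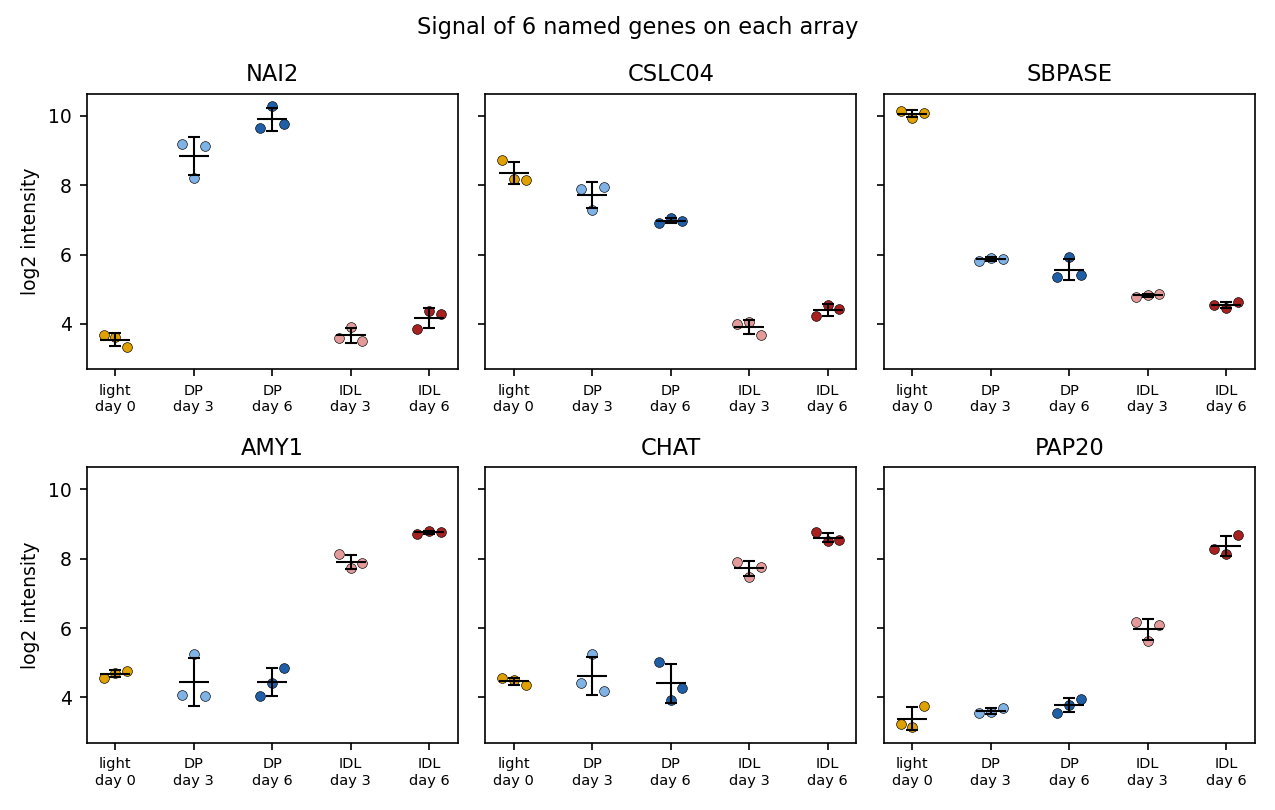
Each panel shows the log2 intensity (vertical axis) of 1 gene in the 5 groups (horizontal axis), with a point per array and the mean ± SD of 3 arrays. NAI2 has means of 8.84 and 9.90 in DP against 3.67 and 4.17 in IDL, and SBPASE falls from 10.06 in light to 5.87 and 5.57 in DP and 4.82 and 4.55 in IDL.

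Day 6 was compared with day 3 within DP leaves to follow the course of darkness. TBL38 (AT1G29050), a trichome birefringence-like gene of wall acetylation, rose by 1.34 ± 0.16 (2.53-fold, adjusted p = 2.52e-05), the glutathione transferase gene GSTF3 (AT2G02930) by 1.25 ± 0.22 and NAI2 by 1.06 ± 0.22 (adjusted p = 0.00543). The light harvesting gene LHB1B2 (AT2G34420) fell by 1.60 ± 0.11 (adjusted p = 5.29e-08), PSBW (AT2G30570) by 1.57 ± 0.15 and the auxin response gene IAA29 (AT4G32280) by 1.55 ± 0.16. Of 7 light harvesting and photosystem genes 4 fell (5 adjusted over the list alone), with a median of -0.55 (adjusted p = 5.49e-07, and 0.00322 with an estimated correlation), which was -0.34 when arrays were centred on the reference genes. Of 13 autophagy genes none rose or fell, also when adjusted over the list alone, while the list was shifted down with a median of -0.24 (adjusted p = 0.000924, but adjusted p = 0.175 with an estimated correlation), which was -0.03 under that centring. Of the other 5 lists none was shifted, and 1 gene of other amino acid breakdown fell, also when adjusted over the list alone, while 2 of 6 proteases and nucleases fell when adjusted over the list alone. ICL stood at 0.21 (adjusted p = 0.439) and ATG8H at -0.27 (adjusted p = 0.364). ICL passed when arrays were centred on the reference genes (0.42, adjusted p = 0.0427). In all, 738 genes (4.6%) changed, 328 higher and 410 lower, and 71 of them at least 2-fold. Centring on the reference genes moved the median of all genes to 0.22 and gave 1580 genes higher and 129 lower, and quantile normalization gave 416 and 387. The count was 420 without replicate 2 of DP at day 6 and 441 without replicate 1 of DP at day 3. Simulated data of DP at day 6 against day 3, with 16174 genes in the fit, gave a recovery of 64% at 1.5-fold and 94% at 2-fold.

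Within IDL leaves, PAP20 rose by 2.40 ± 0.17 from day 3 to day 6 (5.27-fold, adjusted p = 3.12e-09), the zinc finger gene ZAT7 (AT3G46090) by 2.00 ± 0.14 and the heat shock gene Hsp70-2 (AT5G02490) by 1.99 ± 0.14. ECS1 fell by 2.22 ± 0.33 (adjusted p = 0.000105), the expansin gene EXPA16 (AT3G55500) by 1.35 ± 0.21 and the serine carboxypeptidase-like gene SCPL34 (AT5G23210) by 1.29 ± 0.15. ATG8H rose by 0.76 ± 0.14 (adjusted p = 0.00137), and ICL stood at -0.01 (adjusted p = 0.972). Of 7 light harvesting and photosystem genes 2 fell (3 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.0127, but adjusted p = 0.0993 with an estimated correlation), which was -0.07 when arrays were centred on the reference genes. Of 9 genes of branched chain amino acid breakdown 1 fell (2 adjusted over the list alone). Their median was -0.20, which turned to 0.01 when arrays were centred on the reference genes (adjusted p = 0.0253, but adjusted p = 0.324 with an estimated correlation). Of 8 respiration genes 1 rose (2 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.0253, but adjusted p = 0.154 with an estimated correlation and 0.114 after quantile normalization), which was 0.43 under that centring. Each of the last 2 calls was lost without any of 3 arrays. For branched chain amino acid breakdown these were replicates 1 (-0.19, adjusted p = 0.0724) and 2 (-0.17, adjusted p = 0.0681) of day 3 and replicate 2 of day 6 (-0.15, adjusted p = 0.0536). For respiration they were replicate 3 of day 3 (0.17, adjusted p = 0.0869) and replicates 1 (0.23, adjusted p = 0.0735) and 3 (0.17, adjusted p = 0.0551) of day 6. The other 4 lists were not shifted. In all, 1398 genes (8.6%) changed, 779 higher and 619 lower, and 240 of them at least 2-fold. The split was 1744 higher and 154 lower with centring on the reference genes, which moved the median of all genes to 0.17, and 921 and 455 with centring on the median. Without replicate 2 of IDL at day 3 the count was 918. Simulated data of IDL at day 6 against day 3, with 16174 genes in the fit, gave a recovery of 62% at 1.5-fold and 94% at 2-fold.

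The interaction of treatment and day asks whether the change from day 3 to day 6 differed between IDL and DP. EXO changed by -0.79 in DP and by 1.89 in IDL, a difference of 2.68 ± 0.26 (adjusted p = 8.57e-07). The homeodomain gene HAT2 (AT5G47370) changed by -1.43 in DP and by 1.16 in IDL, a difference of 2.59 ± 0.25. MYR2 (AT3G04030), a MYB-related gene, changed by -0.55 and by 1.83, a difference of 2.38 ± 0.16 (adjusted p = 3.32e-09). The sugar transporter gene SWEET4 (AT3G28007) went the other way, at 0.87 in DP and -0.82 in IDL, a difference of -1.69 ± 0.26, and so did GSTF3, at 1.25 and -0.44, a difference of -1.69 ± 0.31. ECS1 had a difference of -1.93 ± 0.47 (adjusted p = 0.0162), lost with an intensity trend (adjusted p = 0.117), without replicate 1 (-1.68, adjusted p = 0.0561) or replicate 3 of DP at day 3 (-1.66, adjusted p = 0.0511) and without replicate 2 of IDL at day 3 (-1.55, adjusted p = 0.0533). ATG8H had a difference of 1.03 ± 0.20 (adjusted p = 0.00326) and ICL of -0.22 (adjusted p = 0.548). Of 13 autophagy genes 1 had a positive difference and none a negative one (3 positive when adjusted over the list alone), with a list median of 0.18 (adjusted p = 0.0261, but adjusted p = 0.25 with an estimated correlation). This call was also lost without replicate 2 of DP at day 3 (0.11, adjusted p = 0.0917) or at day 6 (0.11, adjusted p = 0.0723), without replicate 3 of IDL at day 3 (0.18, adjusted p = 0.0977), after quantile normalization (0.12, adjusted p = 0.104) and with the dim genes left out (adjusted p = 0.0527). The other 6 lists did not pass, but the respiration list (adjusted p = 0.0683) passed without replicate 3 of DP at day 3 (0.35, adjusted p = 0.0443), without replicate 1 of IDL at day 3 (0.28, adjusted p = 0.0489) and without replicate 2 of IDL at day 6 (0.33, adjusted p = 0.0405). In all, 867 genes (5.4%) had an interaction, 507 positive and 360 negative, and 298 of them of at least 2-fold. Centring on the median gave 712 positive and 278 negative. Simulated data of the interaction, with 16174 genes in the fit, gave a recovery of 22% at 1.5-fold, 76% at 2-fold and 100% at 4-fold.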

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

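None of the tests in this part was chosen after its result was seen. The patterns of heat shock genes, ribosomal genes and unnamed probe sets were not among the results planned before the data were examined. They were flagged in these same data, so the shares of random lists do not allow for the choice of list and comparison. The wider gene lists and the fit of all probe sets were added after the annotation had been read. The difference between IDL and DP in the change from day 3 to day 6 passed the test of the interaction itself for 867 genes. Of 100 splits of the arrays 3 gave as many genes, the real one included, and the highest of the others gave 2872. The splits exchanged treatment labels within each day only. In those with 2872 and 2783 genes, day 6 was wholly swapped or left as it was while day 3 was mixed. Their contrast thus took up the difference between IDL and DP at day 6. Such splits do not stand for an absent interaction, so no statement on chance is drawn from them. For gene lists 47 of 100 of these splits gave as many as the real 1, with 3 the highest other. They do not test chance for the same reason, and chance was not excluded. The interaction lists with a call were autophagy with a median of 0.18, cytosolic ribosomal proteins with -0.23, mitochondrial electron transport with 0.18 and heat shock proteins with 0.80. With an estimated correlation the heat shock list held its call (adjusted p = 0.00656), and each of the other 3 had an adjusted p = 0.25.

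Single genes whose interaction passed are given as the day 3 to day 6 change in IDL less that in DP. The positive differences were EXO 2.68, HAT2 2.59, MYR2 2.38, PAP20 2.23, ZAT7 1.86, FAMT 1.74, Hsp70-2 1.73, IAA29 1.35, CSLC04 1.23, PSBW 1.14, LHB1B2 1.03, ATG8H 1.03 and FHL 0.85. The negative differences were LrgB -0.70, XTH33 -1.01, AGL104 -1.11, SWEET4 -1.69, GSTF3 -1.69 and ECS1 -1.93. IAA29 already lay at 3.52 in IDL at day 3, at the lower quartile of that group (3.51), and changed by -0.20 to day 6. Little room was left for a larger fall there, and this limit at low levels was not excluded as the cause of its difference.

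Heat shock protein genes were higher in IDL than in DP at day 6, with 10 of 11 measured genes higher and a list median of 2.04. The lowest median was 1.90 without any 1 of the 6 arrays, which argues against a single array as the whole cause. Under 3 other scalings it was 2.06. These scalings moved the median of all genes only from -0.03 to between -0.016 and 0.021. They could thus not have removed the difference, and no conclusion on other scalings is drawn. Of 10000 random lists of the same size and brightness 0.01% had a median as high, the smallest share they can give, which argues against a general rise of dim genes. The kind of cover (box or foil-coated cover) differed with the treatment, and warmth under it was not measured, so the cause stays open.

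Cytosolic ribosomal protein genes were lower in IDL than in DP at day 6, with 68 of 149 lower and 1 higher and a list median of -0.37 (bootstrap standard error over genes 0.039). The bootstrap resampled genes and not arrays, so this error leaves out the spread between arrays and treats the genes as independent. The highest median was -0.32 under 3 other scalings and -0.31 without any 1 of the 6 arrays, and 0.01% of 10000 random lists of the same size and brightness had a median as low. These values argue against a single array and a general fall of bright genes. The scalings moved all genes little in this comparison and could hardly have removed the difference, so no conclusion on other scalings is drawn. With an estimated correlation the list did not pass (adjusted p = 0.078). No biological explanation was tested.

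Probe sets without a gene in the annotation also changed against light, 4768 in DP at day 3, 5241 in DP at day 6, 5186 in IDL at day 3 and 5241 in IDL at day 6, of 9909. In DP at day 3 this was 48.1% against 35.8% of probe sets with 1 gene. With the latter weighted to the same brightness deciles, the difference went from 12.32 to 3.67 percentage points (bootstrap standard error over probe sets 0.59). Brightness may thus account for most of it. The remaining 3.67 lay above the limit of 2 points set beforehand by more than 2 standard errors. Brightness within a decile was not matched, however, so the test cannot tell whether brightness accounts for all of the difference. Which genes these probe sets measure is not given in the sources used here, and no biological explanation was tested.

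The splits of 6 arrays into groups of 3 number 10, too few for a share under 0.05. In each of the 8 comparisons of a pair of groups the real split called from 738 to 6457 genes, the highest of the others called 0, and 1 of 10 splits was as large. Each other split mixed arrays of both groups, so their difference widened the spread within the fitted groups. The 0 calls can follow from this alone and do not support the real counts. For gene lists, 4 of 10 splits gave as many as the real 6 in DP at day 3 against light, where the highest other gave 6, and 1 of 10 in DP at day 6 (real 6, highest other 5). The values were 1 of 10 in IDL at day 3 (real 5, highest other 4), 2 of 10 in IDL at day 6 (real 5, highest other 5), 1 of 10 in IDL against DP at day 3 (real 5, highest other 3) and 1 of 10 at day 6 (real 3, highest other 2). Over time they were 2 of 10 in DP (real 2, highest other 3) and 1 of 10 in IDL (real 3, highest other 2). Splits that mix arrays of both groups keep part of the difference between them, so lists can still shift there. These list counts thus do not stand for an absent difference, and they say nothing on chance. For the overlap of DP and IDL, 1 of 100 splits gave a count as large as the real 4365 at day 3, with 4105 the highest other, and 1 of 100 as large as the real 4233 at day 6, with 3831 the highest other. The highest other counts come close to the real ones, so these splits carry a structure of the samples, and no statement on chance is drawn from them.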

How the results depend on the processing

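The fit of all probe sets, the wider lists and the families by symbol were chosen after the annotation had been read, and all other alternatives before the data were examined. No named gene that was called changed sign, and no called list changed the direction of its camera test, which is against the other genes. The medians of 8 called lists, 1 of them fixed, changed sign when arrays were centred on the reference genes, among them branched chain amino acid breakdown in IDL over time, from -0.20 to 0.01. Of the comparisons of named genes with an alternative, 9080 stayed on their side of the threshold, 271 lost their call and 3 gained it, all of ICL. Apart from the preset ICL and ATG8H, these genes were picked among called genes of the same data for their large changes. That most held their call or sign therefore does not measure the stability of other calls, and only the preset genes could gain a call. For lists 2304 stayed, 71 lost it, 40 of them with an estimated correlation, and 16 gained it. Of the counts 319 stayed within 1.5 times and 57 moved further. Leaving out 1 array at a time ended 191 of the 271 gene calls lost, centring on the reference genes 38, a fit of only the arrays compared 15, quantile normalization 14, median centring 6 and the intensity trend 4. The replicate numbers were not taken to pair the samples, since 0 of 30 pairs with the same number correlated above 0.1 in their deviations from the group mean (from -0.0776 to 0.0937). A weak link is not excluded. Of 15 arrays 9 went best with their own number, and the median correlation was 0.016 against -0.0098 for other numbers. That median joins unlike pairs. Between darkened groups, pairs of the same number ran from 0.0184 to 0.0937 for replicates 1 and 3 and from -0.0395 to 0.0333 for replicate 2. Pairs of the same number with light ran from -0.0776 to 0.0234. With the replicate number as a block, 3 gene calls were lost (RR16 in DP at day 6 against light, -0.63, AT5G47890 in IDL at day 6 against light, 0.27, and ETFALPHA in IDL against DP at day 6, 0.32) and no count moved by over 1.5 times.

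With a 2-fold minimum the genes changed were 1735 and 2103 in DP at day 3 and day 6 against light, 2018 and 2270 in IDL, 564 and 1115 in IDL against DP, 71 in DP over time, 240 in IDL over time and 298 in the interaction, and the overlap of DP and IDL was 1280 at day 3 and 1314 at day 6. An adjusted p under 0.01 left 316 genes in DP over time, 743 in IDL over time and 426 in the interaction. Both are stricter by construction. The 4 measured reference genes were not steady themselves. GAPC2 fell in all 4 darkened groups, AT4G34270 in DP at both days and AT2G28390 in DP at day 6, while PEX4 rose in DP at day 3 and in IDL at both days. Centring on them raised the median of all genes by construction to 0.17 in DP and 0.25 in IDL at day 3, and by more at day 6. In IDL at day 6 the shift came largely from GAPC2 alone, and list medians that turned there under this centring follow that gene. It called 11176 genes in DP and 11770 in IDL at day 6, 1709 in DP over time and 9127 in the overlap at day 6, and in DP at day 3 it gave 3688 higher and 2172 lower. All probe sets in place of named genes, more units by construction, gave 10801, 12070, 11961 and 12045 against light (DP at day 3 and 6, then IDL), 5416 and 8852 in IDL against DP, 1635 and 2764 over time in DP and IDL, 1852 in the interaction and 8440 and 8131 in the overlap.

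With an estimated correlation the lists shifted were 3 in DP at day 6 against light, 1 in IDL against DP at day 3, 1 in DP over time, 0 in IDL over time and 0 in the interaction, where camera had 2 and 0 lists at an unadjusted p under 0.05. In the interaction 0 lists passed with the dim genes left out and 0 after quantile normalization, with 2 at an unadjusted p under 0.05 in each case. The cause was not tested. The wider lists gave 8 in IDL at day 6 against light, 5 in IDL against DP at day 6, 6 in DP over time and 3 in the interaction, of which 4, 2, 4 and 1 held with an estimated correlation. The families gave 2 and 3 in DP at day 3 and day 6 against light, 3 and 5 in IDL against DP, 0 in IDL over time and 0 in the interaction, where 7 and 7 had an unadjusted p under 0.05. With an estimated correlation 0 families held in each of these, and camera had 3, 2, 3, 3, 4 and 3 at an unadjusted p under 0.05. These are other lists by construction.

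Leaving out 1 array at a time gave 4988 to 5351 genes in DP at day 3, 5758 to 6107 in DP at day 6, 5675 to 6037 in IDL at day 3 and 5884 to 6112 in IDL at day 6 against light, 2189 to 2402 and 3963 to 4405 in IDL against DP, 420 to 602 in DP over time, 918 to 1169 in IDL over time and 655 to 885 in the interaction. The overlap ran from 3866 to 4173 at day 3 and from 3781 to 4046 at day 6. Fewer arrays explain lower counts by construction, but the counts of 420 (without replicate 2 of DP at day 6), 441 (without replicate 1 of DP at day 3) and 918 (without replicate 2 of IDL at day 3) were over 1.5 times below the full fit. Lists shifted ran from 6 to 6 in DP at both days, 4 to 6 in IDL at day 3, 5 to 5 in IDL at day 6, 3 to 5 and 2 to 3 in IDL against DP, 2 to 2 in DP over time, 2 to 2 in IDL over time and 0 to 2 in the interaction. The count in IDL against DP at day 3 was 3 without replicate 1 and without replicate 3 of DP at day 3. In IDL against DP at day 6 it was 2 without replicate 2 of DP or replicate 1 of IDL. The interaction had 0 lists without replicate 2 of DP at either day or replicate 3 of IDL at day 3, each with 3 at an unadjusted p under 0.05, and 2 without replicate 3 of DP at day 3, replicate 1 of IDL at day 3 or replicate 2 of IDL at day 6. Array weights ran from 0.698 to 1.349. Values of signal over background were not used here, so limits for dim genes are unknown, and the simulated data show only that 1.25-fold changes were recovered in 2% to 10% of cases over the 9 comparisons.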

Other observations

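The wider lists in this part were chosen after the annotation had been read and before any gene's value was looked at. Of 26 measured genes for thylakoid proteins of photosynthesis 24 fell in each darkened group against light, with medians of -1.79 and -2.33 in DP at day 3 and day 6 and -2.29 and -2.65 in IDL. NdhU fell by 3.62, NdhN by 3.60 and the calcium sensor gene CaS by 3.38 in DP at day 3. From day 3 to day 6, 9 of 26 fell further in DP and 7 in IDL, with list medians of -0.25 (adjusted p = 0.00741 with an estimated correlation) and -0.38 (adjusted p = 0.0185), which were -0.03 and -0.17 when arrays were centred on the reference genes. All 8 measured genes of the Calvin cycle and photorespiration fell in each darkened group, with medians of -2.08, -2.34, -2.93 and -3.40 in the same order. They were lower in IDL than in DP in 6 cases at day 3 (median -0.995, adjusted p = 0.00177 with an estimated correlation) and in 6 at day 6 with 1 higher (median -1.09, adjusted p = 0.00934). The peroxisomal gene HPR of photorespiration stood at -1.59 and -1.85 in IDL against DP. Plastid ribosomal protein genes fell in 5 of 8 cases in DP at each day and in 8 of 8 in IDL, with medians of -0.79, -0.86, -1.47 and -1.51, with an adjusted p = 0.149, 0.116, 0.0409 and 0.0232 with an estimated correlation. In IDL against DP, 4 and 6 of 8 were lower, with medians of -0.36 and -0.83, and with an estimated correlation neither difference was called (adjusted p = 0.0768 and 0.0858). Tetrapyrrole synthesis fell in 5 of 9 genes in DP at day 3 and in 6 in the other groups, with medians of -0.94, -1.28, -1.25 and -1.28 (adjusted p = 0.0616, 0.0549, 0.0488 and 0.0574 with an estimated correlation).

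Heat shock protein genes were measured for 11 members of the wider list, and the fixed list had no measured member. In IDL at day 6, 10 of 11 were higher than in light, with a median of 2.13 (adjusted p = 1.65e-07, and 0.0232 with an estimated correlation). In IDL at day 3, 3 were higher and 2 lower than in light, and in DP 1 was higher and 1 lower at each day. Against DP at day 6, AT1G07400 was 5.22 higher in IDL, AT5G51440 4.29, AT2G29500 3.46, AT1G53540 2.75 and Hsp70-2 2.15. In DP at day 6 AT2G29500 (3.34) and Hsp70-2 (3.50) lay at or below the lower quartile of all genes (3.51), so their differences are lower bounds. AT1G07400 was already 4.45 higher than light in IDL at day 3. From day 3 to day 6 in IDL, 7 of 11 rose (10 adjusted over the list alone) with a median of 1.13 (adjusted p = 0.0018 with an estimated correlation). Genes of mitochondrial electron transport and ATP synthase fell in 33 and 40 of 59 cases in DP and in 28 and 26 in IDL, with medians of -0.38, -0.54, -0.30 and -0.30, which were -0.24, -0.19, -0.11 and 0.10 when arrays were centred on the reference genes, and with an estimated correlation these calls were lost (adjusted p = 0.0932, 0.052, 0.109 and 0.148). Cytosolic glycolysis fell in 9 and 11 of 17 genes in DP and in 7 and 8 in IDL, with medians of -0.36, -0.63, -0.20 and -0.25, which were -0.23, -0.28, -0.01 and 0.15 under that centring (adjusted p = 0.0252, 0.0135, 0.0409 and 0.0501 with an estimated correlation). Cytosolic ribosomal protein genes fell in 47 and 30 of 149 cases in DP and in 66 and 63 in IDL against light, with medians of -0.12, 0.04, -0.29 and -0.30, which were 0.01, 0.39, -0.10 and 0.10 under that centring, and with an estimated correlation no shift was called there (adjusted p = 0.354, 0.964, 0.101 and 0.114). From day 3 to day 6 in DP, 12 of them rose, with a median of 0.21 (adjusted p = 2.68e-11, and 0.0329 with an estimated correlation), which was 0.43 under that centring. Genes of purine, pyrimidine and asparagine breakdown were called as a list in DP over time, where 2 of 6 fell with a median of -0.17, which turned to 0.05 when arrays were centred on the reference genes (adjusted p = 0.00241, and 0.0248 with an estimated correlation). In DP at day 6 against light 3 of 6 fell, with a median of -0.28 that turned to 0.07 under that centring, and the list lay at the threshold (adjusted p = 0.0505). There it passed under that centring (0.0492), the intensity trend (0.0499), array weights (0.0478), and without replicate 1 (-0.31, 0.0469) or 2 (-0.26, 0.0411) of light and replicate 1 (-0.31, 0.0496) or 2 (-0.25, 0.0481) of DP at day 6, but not with an estimated correlation (adjusted p = 0.0911). Small auxin up RNA genes had 2 measured members and were not tested. Of the 29 families by symbol the autophagy ATG8 proteins rose in 8 and 7 of 9 cases in DP and in 9 and 9 in IDL. With an estimated correlation 0 families passed in any comparison, while camera had from 1 to 5 families at an unadjusted p under 0.05.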
